A study of Mus musculus with 6 samples.

How the data were processed

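RNA was measured by bulk sequencing in cSAM cells, a leukaemia line that arose when mutant SETBP1 and ASXL1 transformed bone marrow of C57BL/6 mice. Per the labels, the cells grew with 1 ng/ml IL-3, received a plasmid with an sgRNA and a puromycin resistance gene, and were kept in 1 µg/ml puromycin for 4 days before RNA extraction. Of the 6 libraries, 3 came from cells with a non-targeting sgRNA (control) and 3 from cells with an sgRNA against Setdb1. Per the labels' protocols, ribosomal RNA was removed with RNase H and the libraries kept strand information through dUTP. The labels call the replicates of a group biological replicates without saying whether they were transduced separately, so p-values measure the spread between these samples.

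The deposited values are CPM, the counts of a gene per 1000000 reads assigned to the listed genes, for 25239 gene symbols without duplicates. The submitters' processing notes list the mm10 genome and edgeR 3.32.1 with no role. The aligner, the counter, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of close paralogs were taken as the authors assigned them. Each deposited CPM column summed to 1000000, which leaves no room for a TMM factor. In each library 100.0% of the values were whole multiples of the CPM of 1 read, within 0.001 read, so the reads behind them could be recovered. The recovered totals were 43144739, 42668475 and 42777824 reads in control replicates 1, 2 and 3, and 40093577, 41387803 and 40849822 in Setdb1-sgRNA replicates 1, 2 and 3. At that depth 3 reads correspond to 0.0695 to 0.0748 CPM in 1 library. For a gene with no read in any control library, the fold is a lower bound against 3 reads over the whole group, and it covers counting error only. The table held no mitochondrially encoded genes, and 6780 symbols were at 0 in all 6 libraries. No replicate pair was a duplicate, as the chi-square of reads over degrees of freedom was 8.49 to 13.1 within the Setdb1-sgRNA group and 37.8 to 97.9 within the control group.

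The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend on log2(CPM + 0.5), over the 11920 genes with a mean of at least 0.5 CPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Setdb1 sgRNA minus control on that scale and understate the change of low genes; folds are ratios of mean CPM. Adjusted p-values are limma's unless another tool is named. The 26 gene lists were fixed before the data were examined. The 25 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Shares of reads were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3. Because the reads could be recovered, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on them as alternatives; 2 genes had no adjusted p from DESeq2. Further alternatives planned before the data were examined were other pseudocounts, filters, scalings and variance models, a block for the replicate number, and leaving out each library. Removing the trend of each library on transcript length and GC content, keeping only control replicate 3, and leaving Rpph1 out of the totals were added after the data were seen. Length and GC content came from the longest GENCODE M21 transcript and were available for 98% of tested genes.

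The genes named in the text follow a rule set in advance. It takes Setdb1, and the 8 genes with the largest rise and the 8 with the largest fall that passed the threshold, had no overlap between the groups and reached 5 CPM in the higher group, leaving out uncharacterised loci and pseudogenes. It also takes, from each list, up to 4 members that passed with the largest change and at least 1 CPM, or the 2 most abundant where none passed, and the most abundant member of each list of another cell type. Other genes are said to have been chosen after their values were seen. Gene positions are RefSeq spans on GRCm38, the assembly behind mm10, matched by symbol for 99.2% of the table.

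The tests were checked on simulated data for the same comparison, with 11920 genes of which 200 were changed. Limma called 80.6% of the genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, with 12 false among 192 calls. The edgeR test gave 82.1%, 89.6% and 100% with 11 false calls, and DESeq2 gave 85.1%, 89.6% and 100% with 22 false among 205 calls. In a simulated shift of 1 list, that list was called and 0 of the other lists were. The simulated genes were drawn independently of each other. That check therefore does not cover correlation between list members, which was estimated at up to 0.266 in the data. Both simulated groups had the same dispersion per gene, and no length trend between libraries was added. In the data the median SD per gene was 0.154 in control and 0.0678 in Setdb1-sgRNA cells (log2 scale), and 19% of tested genes were called. The simulated false calls therefore do not give the error rate of the real fit.

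Adjacent raised genes were counted along the tested genes with a RefSeq position, and compared with 10000 permutations within 10 bins of mean expression. Genes counted as different families only if the first 2 letters of their symbols differed and neither was an uncharacterised locus or a zinc finger gene. This rule replaced narrower ones after their results had been seen, since these let paralogs such as Lilr4b and Lilrb4a pass as different families; comparing the letters before the first digit gave 14 pairs (permutation p = 0.0001) in place of 6 (permutation p = 0.0057). For the granule genes, smaller sets picked by hand were replaced by whole lists after their first values had been seen, because they left out called genes.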

Results

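Gene expression was measured by rRNA-depleted, stranded RNA sequencing in mouse cSAM leukaemia cells with a non-targeting sgRNA (control, n = 3) or with an sgRNA against Setdb1 (n = 3), after puromycin selection. Setdb1 encodes a histone methyltransferase that places H3K9 trimethylation. The libraries held 40093577 to 43144739 reads assigned to genes. The comparison asked which genes change when Setdb1 is depleted, and the study's title puts interferon responses and recognition by NK cells at its centre. Only 1 sgRNA against Setdb1 was measured.

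Setdb1 mRNA (mm10 chromosome 3, 95323525 to 95357202) fell from 96.5 ± 8.74 CPM in control to 63.9 ± 2.37 CPM in Setdb1-sgRNA cells (mean ± SD, n = 3 each). The control libraries stood at 86.8, 98.8 and 103.8 CPM and the Setdb1-sgRNA libraries at 62.4, 62.6 and 66.6 CPM, with no overlap. The log2 fold change was −0.59 with an SE of 0.08 and an adjusted p of 0.00121. Transcripts of edited alleles can persist, so the RNA level checks the depletion only in part.

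Of 11920 tested genes, 1439 were higher and 826 lower in Setdb1-sgRNA cells. The rises were larger than the falls: 176 genes rose and 37 fell by a log2 fold change of at least 1, and on the same log2(CPM + 0.5) scale 50 rose and 0 fell by at least 4-fold. In 41.4% of tested genes the groups did not overlap, against 10% by chance. On the CPM as deposited 63.5% of calls were higher, but after TMM scaling 1159 were higher and 1028 lower (53%), with DESeq2 46.5% were higher and with edgeR 50.4%. Of the limma calls, 1970 were shared with edgeR, all with the same sign. The counts varied when 1 library was left out. They were 1441 and 847 without control replicate 1, 704 and 321 without control replicate 2, and 2983 and 1839 without control replicate 3. Without any 1 of Setdb1-sgRNA replicates 1, 2 and 3, between 548 and 605 were higher and between 229 and 269 lower. Leaving out a library also lowers power, so a lost call does not by itself show a changed fold. Relative to its size, the log2 fold change of called named genes moved most in Nkg7 (−0.86 to −0.56), Ccne2 (0.48 to 0.31) and H2ac11 (−0.37 to −0.24). Of 93 called genes in the naming rule other than Setdb1, 70 kept their call in each fit that left out 1 library. The other 23 lost it without single libraries, which are given where these genes are named, and are called less firm there. Of these, Cd274, Psme1, Il27, Gp9, Flt3, Ccne2, Cdk1, Tyms, Cdc45, H1f1 and Hist1h2al also lost the call against control replicate 3 alone, a fit added after the data were seen. That fit takes its spread from the Setdb1-sgRNA libraries only. These varied less than the control libraries (median SD per gene of 0.0678 against 0.154 on the log2 scale). Its calls, counts and adjusted p, here and below, therefore do not measure the spread between controls.

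Among genes that reached 5 CPM in the higher group, the 8 largest rises by log2 fold change included genes with next to no reads in control cells. Fbp2 and Fbp1, neighbouring genes for the gluconeogenic enzyme fructose-1,6-bisphosphatase on chromosome 13 (62836884 to 62858400 and 62864753 to 62888298), rose from 0.07 ± 0.12 to 35.0 ± 0.205 CPM and from 0.109 ± 0.0131 to 22.98 ± 0.716 CPM, with adjusted p of 5.64e-09 and 2.45e-09. Control replicate 1 held all control reads of Fbp2. Urml (chromosome 13, 68228435 to 68234731) and Sec14l4 (chromosome 11, 4031378 to 4048426) had no read in any control library and reached 11.6 ± 1.62 and 8.48 ± 0.602 CPM, at least 497-fold and 363-fold higher. Pla2g5, a secreted phospholipase (chromosome 4, 138799247 to 138863562), rose 22.9-fold from 1.51 ± 0.427 to 34.6 ± 0.51 CPM (adjusted p = 5.44e-08). The serpin gene Serpinb9g rose 74.5-fold to 13.9 ± 1.53 CPM, and 149-fold without control replicate 2. The zinc finger genes Zfp970 and Zfp972, 2 members of a family on distal chromosome 2, rose 26.3-fold and 29.6-fold. Fbp2 and Fbp1 are of one family, and Serpinb9g and these zinc finger genes have close paralogs. How reads shared between such genes were assigned is not known.

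The 8 largest falls by log2 fold change were taken from genes with at least 5 CPM in control cells, which leaves out less expressed genes with larger folds. Mpo, the myeloperoxidase of primary neutrophil granules (chromosome 11, 87793784 to 87804412), fell from 6980 ± 927 to 1900 ± 73.3 CPM, 3.67-fold (adjusted p = 2.09e-06). Its neighbour Lpo, lactoperoxidase, fell 3.61-fold to 1.52 ± 0.33 CPM, and Elane, neutrophil elastase, fell 3.51-fold from 77.8 ± 9.66 to 22.2 ± 1.86 CPM. Rgcc, a regulator of the cell cycle, fell 3.76-fold from 269.7 ± 60.7 to 71.7 ± 6.64 CPM. Olr1, a scavenger receptor for oxidised LDL, fell 3.83-fold, Cth, which makes cysteine from cystathionine, 3.13-fold, Cables1 3.27-fold and Heg1 2.81-fold, with adjusted p between 2.09e-06 and 0.000335 over these 8 genes.

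**Figure D1:**
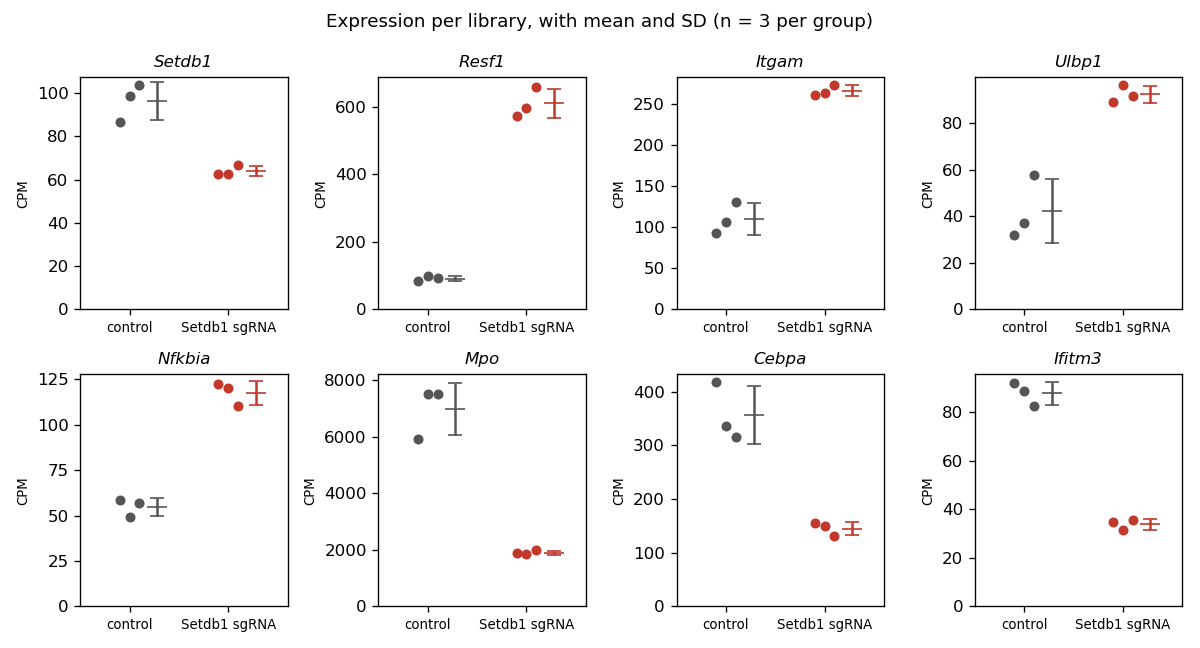
Expression in CPM of 8 genes in each control (grey) and Setdb1-sgRNA (red) library, with the group mean and SD beside the points (n = 3 per group) and the vertical axes starting at 0. Setdb1, Mpo, Cebpa and Ifitm3 were lower and Resf1, Itgam, Ulbp1 and Nfkbia higher in each Setdb1-sgRNA library than in any control library.

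The interferon-stimulated genes did not move together. Of 31 tested type I interferon-stimulated genes, 3 rose, 2 fell and 26 did not pass (4 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.946, and 0.949 with an estimated correlation). The balance depended on the scaling and the tool: 3 rose and 4 fell after TMM scaling and with edgeR, and 3 and 5 with DESeq2. The ubiquitin-activating enzyme for ISG15, Uba7, rose 1.63-fold to 101.4 ± 1.67 CPM, and Samd9l rose 1.47-fold, a less firm call (adjusted p of 0.0584 without control replicate 2 and of 0.0632, 0.0751 and 0.0665 without Setdb1-sgRNA replicates 1, 2 and 3), with a log2 fold change of 0.31 against control replicate 3 alone and 0.55 with all libraries. The antiviral membrane protein gene Ifitm3 fell 2.59-fold, from 87.9 ± 4.78 to 33.9 ± 2.29 CPM (adjusted p = 3.11e-06), and Cmpk2 fell 2.64-fold. Parp9, named after its value was seen, rose 1.39-fold (adjusted p = 0.0195), a less firm call. Its adjusted p was 0.0836 without control replicate 2 and 0.0521, 0.0956 and 0.0884 without Setdb1-sgRNA replicates 1, 2 and 3. It was 0.0864 against control replicate 3 alone, where the log2 fold change went from 0.47 to 0.23. Isg15, named likewise, stood at 2.40 ± 1.14 CPM in control and 1.99 ± 0.195 CPM in Setdb1-sgRNA cells without passing the test (adjusted p = 0.661). Against control replicate 3 alone, the median log2 fold change of the type I genes was 0.05, compared with 0.08 with all libraries. Of 13 tested interferon gamma-inducible genes, 3 rose and 2 fell (the same adjusted over the list alone, with a camera adjusted p of 0.397). Against control replicate 3 alone the median log2 fold change of these genes went from −0.06 to −0.29. Among them, Irf8, a transcription factor of the monocyte and dendritic cell lineages, fell 1.65-fold to 57.8 ± 1.78 CPM, Gbp3 fell 1.68-fold, the adhesion molecule gene Icam1 rose 1.47-fold, and Cd274, which encodes PD-L1, rose 2.84-fold from 0.544 ± 0.312 to 1.545 ± 0.0246 CPM, a less firm call (adjusted p of 0.0535 and 0.0514 without Setdb1-sgRNA replicates 2 and 3). Its log2 fold change was 0.56 against control replicate 3 alone and 1.01 with all libraries. Ifi47, named after its value was seen, rose 1.22-fold, also less firm. Without control replicate 2 its adjusted p was 0.119, without Setdb1-sgRNA replicates 1, 2 and 3 it was 0.0827, 0.167 and 0.124, and against control replicate 3 alone 0.065. Of the 24 interferon and receptor genes 15 were at 0 in all libraries and only 7 were tested. Among the 7 tested, 2 rose and 0 fell (3 and 0 adjusted over the list alone, with a camera adjusted p of 0.325). These were Ifngr2, 1.4-fold to 103.4 ± 4.55 CPM, and the kinase gene Jak1, 1.29-fold to 250.8 ± 1.95 CPM.

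Sensors of nucleic acids were higher as a list. Of 20 tested members 8 rose and 0 fell (the same adjusted over the list alone; 10 and 0 at an unadjusted p under 0.05, 7 and 0 with edgeR and with DESeq2), with a camera adjusted p of 0.0111, which became an adjusted p of 0.521 with an estimated correlation. Ifi213, of the AIM2-like receptor family, rose 3.29-fold from 47.2 ± 5.48 to 155.2 ± 2.58 CPM (adjusted p = 9.81e-07). Ddx58, which encodes the RNA sensor RIG-I, rose 1.63-fold to 30.4 ± 1.8 CPM, Ifi203 rose 1.63-fold and Sting1, the adaptor of cytosolic DNA sensing, rose 1.58-fold to 83.7 ± 1.95 CPM.

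Ligands that NK cells read on target cells were higher as a list. Of 16 tested members 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.51 and a camera adjusted p of 0.0013, which became an adjusted p of 0.265 with an estimated correlation. The NKG2D ligand genes Raet1d and Ulbp1 rose 4.12-fold, from 1.95 ± 0.287 to 8.05 ± 0.437 CPM (adjusted p = 1.58e-05), and 2.19-fold, from 42.2 ± 13.6 to 92.3 ± 3.71 CPM (adjusted p = 0.00162). H60b, a further NKG2D ligand gene, rose 2.41-fold, a less firm call (adjusted p of 0.0668 without control replicate 2 and of 0.119 and 0.126 without Setdb1-sgRNA replicates 2 and 3), and Clec2i, which encodes a ligand of NKR-P1 receptors, rose 2.25-fold to 1.626 ± 0.0488 CPM. Against control replicate 3 alone the log2 fold change of Ulbp1 was 0.67, compared with 1.17 with all libraries. Raet1d and H60b have close paralogs. The only fall, named after its value was seen, was in Tnfsf10, which encodes TRAIL, from 2.74 ± 0.367 to 1.47 ± 0.0443 CPM, a less firm call (adjusted p of 0.0506 without Setdb1-sgRNA replicate 3). Without control replicates 1 and 2, a fit added after the data were seen, the median log2 fold change of the NK ligand genes was 0.605, compared with 0.507.

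Antigen presentation genes showed few changes. Of 22 tested MHC class I genes 1 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.197), and 3 rose and 1 fell against control replicate 3 alone. The class I heavy chain gene H2-D1 rose 1.38-fold to 113.3 ± 3.58 CPM, while the immunoproteasome gene Psmb10 fell 1.65-fold to 74.4 ± 5.66 CPM and Psme1 fell 1.35-fold, a less firm call (adjusted p of 0.121 without control replicate 2 and of 0.0897, 0.0971 and 0.104 without Setdb1-sgRNA replicates 1, 2 and 3). The log2 fold change of Psme1 went from −0.42 to −0.13 against control replicate 3 alone. Of 7 tested MHC class II genes 1 rose and 0 fell (3 and 1 adjusted over the list alone, and 2 and 0 against control replicate 3 alone; camera adjusted p = 0.946), with a median of −0.12 and a mean of 0.06 on the log2 scale and a downward camera direction. The median turned to 0.02 against control replicate 3 alone and was −0.02 with the length and GC trend removed. The gene that rose was H2-DMb1, 1.39-fold to 20.2 ± 0.976 CPM, a less firm call (adjusted p of 0.0527 and 0.053 without Setdb1-sgRNA replicates 2 and 3).

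NF-κB targets were higher as a list. Of 16 tested members 11 rose and 1 fell (13 and 2 adjusted over the list alone), with a camera adjusted p of 0.000363, which became an adjusted p of 0.265 with an estimated correlation. After TMM scaling, with edgeR and with DESeq2, 9 rose and 2 fell. Nfkbia, the inhibitor that NF-κB induces, rose 2.15-fold from 54.7 ± 4.97 to 117.6 ± 6.46 CPM, and the subunit genes Relb and Rel rose 1.79-fold and 1.52-fold. Ier3 rose 1.67-fold. The gene that fell in the main test, named after its value was seen, was Bcl3, 1.44-fold lower (adjusted p = 0.0272), a less firm call. Its adjusted p was 0.115 without control replicate 2 and 0.0586, 0.123 and 0.0893 without Setdb1-sgRNA replicates 1, 2 and 3. It was 0.217 against control replicate 3 alone, where the log2 fold change went from −0.50 to −0.20. Of 9 tested chemokine and cytokine genes 2 rose and 0 fell (the same adjusted over the list alone, and 1 and 0 against control replicate 3 alone; camera adjusted p = 0.99), with a median of −0.14 and a mean of 0.16 on the log2 scale and an upward camera direction. Here too the median turned against control replicate 3 alone, to 0.10. Tnf rose 1.92-fold, from 83.7 ± 17.5 to 160.5 ± 16.3 CPM (adjusted p = 0.00151), and Il27 rose 2.24-fold to 2.04 ± 0.257 CPM, a less firm call that edgeR did not make (adjusted p = 0.0726), with an adjusted p of 0.11 without control replicate 2 and of 0.0993, 0.0996 and 0.137 without Setdb1-sgRNA replicates 1, 2 and 3. Il27 was 3.43-fold higher without control replicate 3. Against control replicate 3 alone its log2 fold change went from 0.93 to 0.31.

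Myeloid markers moved in both directions. Of 25 tested monocyte and macrophage markers 9 rose and 2 fell (10 and 4 adjusted over the list alone, and 9 and 4 against control replicate 3 alone; camera adjusted p = 0.35). The chemokine receptor gene Ccr2 rose 3.43-fold to 10.6 ± 0.662 CPM, the Fc receptor gene Fcgr1 3.38-fold, the integrin gene Itgam, which encodes CD11b, 2.42-fold from a mean of 110.0 CPM (92.6, 106.9 and 130.6 in the control libraries) to 266.6 ± 6.46 CPM (adjusted p = 3.99e-05), and the M-CSF receptor gene Csf1r 1.93-fold to 62.9 ± 1.93 CPM. The falls, named after their values were seen, were in Ms4a3 and Ms4a6c, 1.57-fold and 1.9-fold. Of 20 tested granulocyte markers 8 rose and 6 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.946). Besides Mpo, the rule named Ltf, lactoferrin of the secondary granules, which rose 9.22-fold to 3.51 ± 0.398 CPM, Mmp9, 7.21-fold to 3.20 ± 0.39 CPM, and S100a8, 10.4-fold to 2.10 ± 0.28 CPM. All 3 stayed far below Mpo in level. Without control replicate 3 the fold was 25.7 for S100a8, and without control replicate 2 it was 11 for Mmp9.

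Stem cell, progenitor and leukaemia genes also moved both ways, with 5 of 27 higher and 6 lower (9 and 8 adjusted over the list alone, and 5 and 10 against control replicate 3 alone; camera adjusted p = 0.325). Cebpa, a transcription factor of granulocyte and monocyte commitment, fell 2.46-fold from 356.7 ± 54.5 to 145.1 ± 12.3 CPM (adjusted p = 3.87e-05). The stem cell factor receptor gene Kit fell 1.95-fold to 66.1 ± 1.44 CPM and Prom1 fell 2.11-fold, while Cd34 rose 2.22-fold from 3.18 ± 0.171 to 7.05 ± 0.264 CPM. The other rises, named after their values were seen, were in Pbx3, Hoxa6 and Meis1, 1.56-fold, 1.48-fold and 1.31-fold, and in Flt3, described with the dendritic cell markers. Pbx3, Hoxa6 and Meis1 were less firm: their adjusted p was 0.0579, 0.0591 and 0.0943 without Setdb1-sgRNA replicate 1, 0.0681, 0.0601 and 0.104 without replicate 2 and 0.116, 0.0624 and 0.123 without replicate 3. Without control replicate 2 it was 0.0696 for Pbx3 and 0.0505 for Hoxa6. Control replicate 3 alone gave an adjusted p of 0.0504 for Pbx3 and a log2 fold change of 0.34 for Hoxa6, compared with 0.55.

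Markers of other lineages were mostly low. Of 6 tested mast cell, basophil and eosinophil markers 0 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.0564), among them Mcpt8, the most abundant, 1.78-fold to 3.02 ± 0.365 CPM, and Siglecf, 1.66-fold, a less firm call (adjusted p of 0.0686, 0.0512 and 0.057 without Setdb1-sgRNA replicates 1, 2 and 3). Cpa3, named after its value was seen, fell 4.86-fold. Without Setdb1-sgRNA replicate 3 the fall was 10.2-fold. It was a less firm call (adjusted p of 0.0726 without control replicate 2 and of 0.0749 and 0.0742 without Setdb1-sgRNA replicates 1 and 2). Camera called this list as lower without control replicate 1 (adjusted p = 0.0378), without Setdb1-sgRNA replicate 3 (adjusted p = 0.014) and with the replicate number as a block (adjusted p = 0.0307). Other settings moved camera's adjusted p up, to 0.267 without control replicate 3, 0.104 without Setdb1-sgRNA replicate 1 and 0.0904 after TMM scaling. The median log2 fold change of the list was −0.463 against control replicate 3 alone and −0.355 with all libraries. Of 9 erythroid and megakaryocyte markers 2 rose and 1 fell (the same adjusted over the list alone, and 1 and 1 against control replicate 3 alone; camera adjusted p = 0.946, in the downward direction although the median was 0.07). That median turned to −0.08 against control replicate 3 alone and to −0.0031 with edgeR. The most abundant, Car2, rose 1.6-fold from 963.1 ± 52.2 to 1543 ± 23.2 CPM, while the less firm calls were Gp9, which rose 2.14-fold, and the transferrin receptor gene Tfrc, which fell 1.19-fold. Without control replicate 2 the adjusted p was 0.0543 for Gp9 and 0.0865 for Tfrc; without Setdb1-sgRNA replicates 2 and 3 it was 0.0535 and 0.0646 for Gp9, and without Setdb1-sgRNA replicates 1, 2 and 3 it was 0.165, 0.069 and 0.168 for Tfrc. Of 7 dendritic cell markers 3 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.325), including Zbtb46, 2.01-fold to 6.07 ± 0.521 CPM, and the less firm Clec10a, 1.62-fold, and Flt3, the most abundant, 1.23-fold to 794.3 ± 10.7 CPM. Without Setdb1-sgRNA replicates 1, 2 and 3 the adjusted p was 0.0524, 0.104 and 0.0674 for Clec10a and 0.0995, 0.111 and 0.119 for Flt3, and without control replicate 2 it was 0.104 for Flt3. With control replicate 3 as the only control, log2 fold changes went from 0.95 to 0.46 for Gp9 and from 0.30 to 0.16 for Flt3. Only 2 lymphoid markers were tested, too few for camera: Nkg7 fell 3.07-fold to 0.393 ± 0.0714 CPM, a less firm call (adjusted p of 0.114 without control replicate 2, of 0.096, 0.141 and 0.132 without Setdb1-sgRNA replicates 1, 2 and 3, and of 0.0702 with the length and GC trend removed) and the same adjusted over the list alone. Its log2 fold change went from −0.86 to −0.56 without control replicate 2. Cd79b, the most abundant, stood at 26.2 ± 4.43 and 28.9 ± 2.21 CPM (adjusted p = 0.398).

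Ribosome biogenesis and Myc-linked genes were lower. Of 25 tested members 0 rose and 13 fell (0 and 17 adjusted over the list alone, at an unadjusted p under 0.05, with edgeR and with DESeq2), with a median log2 fold change of −0.27 and a camera adjusted p of 1.71e-07, which became an adjusted p of 0.0853 with an estimated correlation. The correlation estimated for this list was 0.0033, below the preset 0.01, so correlation between its members does not account for that loss. With all libraries, Npm1, nucleophosmin, fell 1.55-fold from 297.1 ± 48.9 to 192.2 ± 11.7 CPM, Ncl, nucleolin, 1.43-fold from 910.0 ± 103 to 635.9 ± 41.5 CPM, Nop16 1.46-fold, and Rrs1 1.47-fold, a less firm call (adjusted p of 0.0707 without control replicate 2 and of 0.0583, 0.0827 and 0.0925 without Setdb1-sgRNA replicates 1, 2 and 3). Log2 fold changes went from −0.62 to −0.33 for Npm1 and from −0.54 to −0.27 for Rrs1 against control replicate 3 alone. The median of the list was −0.233 there, compared with −0.266. Of 34 cell cycle genes 4 rose and 1 fell, but 0 in either direction adjusted over the list alone (camera adjusted p = 0.634), against 9 and 1 at an unadjusted p under 0.05, 2 and 1 with edgeR and 4 and 1 with DESeq2. The rises, 1.25-fold in Cdc45, 1.26-fold in Tyms, 1.3-fold in Cdk1 and 1.39-fold in Ccne2, were all less firm. Without control replicate 2 their adjusted p was 0.116, 0.0796, 0.172 and 0.0796, without Setdb1-sgRNA replicates 1, 2 or 3 it lay between 0.0876 and 0.165, and without control replicate 1 it was 0.0733 for Cdk1. Against control replicate 3 alone, 0 cell cycle genes rose and 0 fell, and the log2 fold change went from 0.40 to 0.07 for Cdk1, from 0.33 to 0.14 for Cdc45, from 0.34 to 0.19 for Tyms and from 0.48 to 0.28 for Ccne2, so these calls were made only with control replicates 1 or 2 included. For Ccne2 it was 0.31 without control replicate 1, and with the length and GC trend removed its adjusted p was 0.0773. The fall, named after its value was seen, was in Mybl2, 1.16-fold (adjusted p = 0.0497). It was not called without any 1 of the libraries other than control replicate 3 (adjusted p between 0.0589 and 0.188), nor against control replicate 3 alone (adjusted p = 0.0663). With edgeR the adjusted p was 0.069 for Cdk1 and 0.0571 for Ccne2. Of 24 p53 targets 4 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.35), with Trp53inp1, Btg2 and Sesn1 1.86-fold, 1.85-fold and 1.46-fold higher and Trp53cor1 1.61-fold higher, a less firm call (adjusted p of 0.0599 without control replicate 2 and of 0.0635 and 0.0876 without Setdb1-sgRNA replicates 1 and 3). Its log2 fold change went from 0.66 to 0.41 against control replicate 3 alone. Zmat3, named after its value was seen, was 1.18-fold lower, a less firm call. Its adjusted p was 0.0869 without control replicate 2 and 0.125, 0.136 and 0.111 without Setdb1-sgRNA replicates 1, 2 and 3. With control replicate 3 as the only control, the p53 targets had a median log2 fold change of 0.11, compared with 0.083 with all libraries. Of 24 genes of the integrated stress and unfolded protein responses 4 rose and 3 fell (the same adjusted over the list alone, and 6 and 2 against control replicate 3 alone; camera adjusted p = 0.946, in the downward direction although the median was 0.02, −0.03 after TMM scaling and −0.04 with edgeR). Herpud1 and Pdia4 rose 1.5-fold and 1.37-fold, Dnajb9 rose 1.39-fold, a less firm call (adjusted p of 0.0686 and 0.0644 without Setdb1-sgRNA replicates 2 and 3), and Ddit4 fell 1.41-fold. Named after their values were seen, Hspa5 rose 1.31-fold, and Atf4 and Atf5 fell 1.24-fold and 1.21-fold, all less firm. Their adjusted p was 0.0672, 0.0749 and 0.132 without control replicate 2, and without Setdb1-sgRNA replicates 1, 2 or 3 it lay between 0.0611 and 0.181. For Atf5 it was also 0.0631 without control replicate 1, 0.114 with the length and GC trend removed and 0.206 against control replicate 3 alone, where the log2 fold change went from −0.27 to −0.12.

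**Figure D2:**
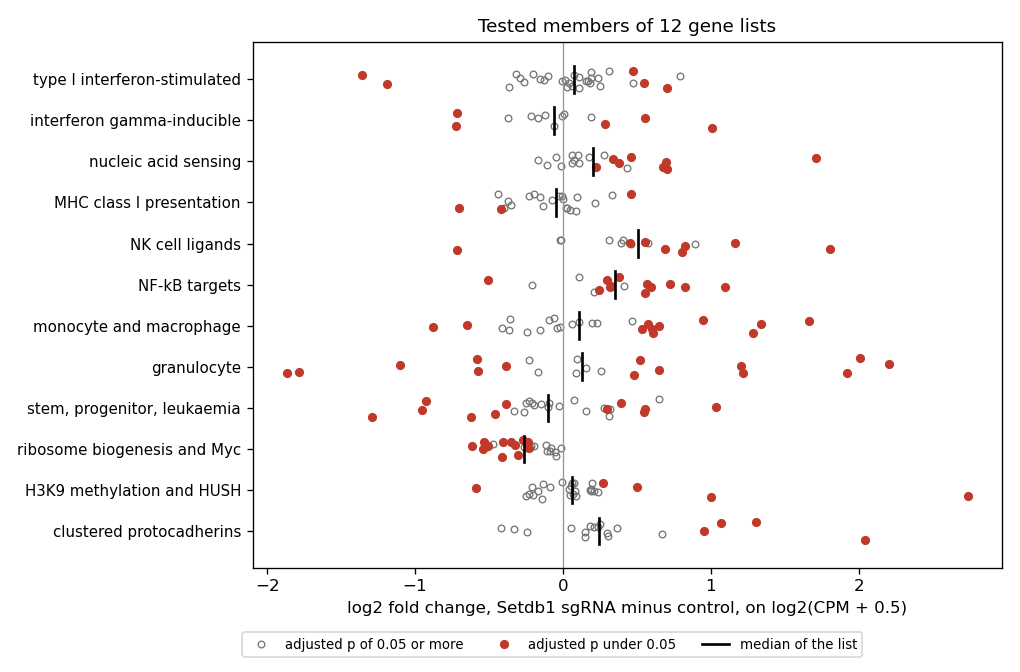
Log2 fold change of each tested member of 12 gene lists (horizontal axis, Setdb1 sgRNA minus control on log2(CPM + 0.5), 3 libraries per group), with filled points for adjusted p under 0.05, open points for the rest and a black bar at the median of each list. Ribosome biogenesis genes lie below 0 (0 higher, 13 lower of 25), NK cell ligands and NF-κB targets lie mostly above 0, and granulocyte markers spread from −1.87 to 2.20.

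Among 28 tested genes of H3K9 methylation and the HUSH complex, a silencing complex that works with Setdb1, 4 rose and 1, Setdb1 itself, fell (the same adjusted over the list alone, and 5 and 2 against control replicate 3 alone; camera adjusted p = 0.572). Resf1 (chromosome 6, 149309409 to 149335663), a factor known to act with Setdb1 in retroelement silencing, rose 6.7-fold from 90.99 ± 7.47 to 609.9 ± 43.9 CPM (adjusted p = 2.09e-08). Atf7ip (chromosome 6, 136518789 to 136610850), the partner that stabilises Setdb1 protein, rose 2.01-fold from 122.6 ± 10.1 to 246.0 ± 10.7 CPM, and Tasor, a HUSH subunit gene, rose 1.42-fold. Morc3, named after its value was seen, rose 1.21-fold. It was less firm (adjusted p of 0.0695 without control replicate 2 and of 0.0915, 0.118 and 0.13 without Setdb1-sgRNA replicates 1, 2 and 3). Of the 58 germline genes 20 were at 0 in all libraries and 9 were tested, of which 1, Tdrd5, rose 4.58-fold to 1.25 ± 0.18 CPM, and 8.23-fold without control replicate 2 (the same adjusted over the list alone; camera adjusted p = 0.625).

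Of 18 tested clustered protocadherin genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0249, and an adjusted p of 0.521 with an estimated correlation). They include Pcdhgb5, 4.64-fold from 3.06 ± 0.164 to 14.2 ± 0.513 CPM, Pcdhgb7, 2.88-fold, and Pcdhga9, 3.35-fold, which share 3′ exons on chromosome 18 and so can share reads, as does Pcdhga11, named after its value was seen, 3.79-fold. Pcdhga11 was 6.74-fold higher without control replicate 3. It was less firm (adjusted p of 0.0816 without control replicate 2, of 0.0977 and 0.0871 without Setdb1-sgRNA replicates 1 and 3, and of 0.136 against control replicate 3 alone). That fit took the log2 fold change from 0.95 to 0.56 for Pcdhga11 and from 1.07 to 0.67 for Pcdhga9. Of 302 tested zinc finger genes with Zfp names 29 rose and 7 fell (22 and 6 adjusted over the list alone; camera adjusted p = 0.0111, and an adjusted p of 0.759 with an estimated correlation). Over all 11920 tested genes 1439 rose and 826 fell, so calls in either direction were rarer among the zinc finger genes. Their median log2 fold change was 0.137, compared with 0.0448 over all tested genes. Besides Zfp970 and Zfp972, Zfp971 rose 4.88-fold from 30.6 ± 0.939 to 149.1 ± 11.9 CPM and Zfp469 6.19-fold to 5.58 ± 0.298 CPM. The balance of the zinc finger genes depended on the scaling: 23 rose and 11 fell after TMM scaling, 23 and 13 with edgeR and 29 and 19 with DESeq2, while 18 rose and 7 fell against control replicate 3 alone. The zinc finger list was not called without control replicate 1 (adjusted p = 0.109), against control replicate 3 alone (adjusted p = 0.708), or by fry (adjusted p = 0.086). The protocadherin list was not called without control replicate 1 (adjusted p = 0.0826), without Setdb1-sgRNA replicate 1 (adjusted p = 0.0568) or against control replicate 3 alone (adjusted p = 0.161). With the length and GC trend removed, the adjusted p was 0.0661 for both lists. Of 9 imprinted genes 0 passed with limma, edgeR or DESeq2, adjusted over the list alone, or at an unadjusted limma p under 0.05 (camera adjusted p = 0.655). The most abundant, Gnas and Kcnq1ot1, gave no call with all libraries: Gnas stood at 571.7 ± 16 and 569.8 ± 12.3 CPM and Kcnq1ot1 at 68.8 ± 20.8 and 62.1 ± 10.4 CPM. Against control replicate 3 alone the log2 fold change of Kcnq1ot1 was −0.47, compared with −0.11 with all libraries. Its control libraries stood at 45.45, 75.89 and 85.14 CPM, so the value depends on which control is kept.

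Of 55 tested replication-dependent histone genes 0 rose and 6 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.000701, and an adjusted p of 0.521 with an estimated correlation; fry adjusted p = 0.152). At an unadjusted p under 0.05 2 rose and 17 fell, with edgeR 0 and 7, and with DESeq2 0 and 14. The rule named H1f2, H1f1, Hist1h2al and H2ac11, 1.75-fold, 1.4-fold, 1.36-fold and 1.3-fold lower and all less firm. Their adjusted p was 0.114, 0.152, 0.076 and 0.0624 without control replicate 2 and between 0.0593 and 0.155 without Setdb1-sgRNA replicates 1, 2 or 3, and that of H1f1 was 0.0605 without control replicate 1. With the length and GC trend removed, the log2 fold change of Hist1h2al went from −0.43 to −0.08 (adjusted p = 0.684). Control replicate 3 alone gave log2 fold changes of −0.22 for H1f2, −0.12 for H1f1, −0.25 for Hist1h2al and −0.24 for H2ac11, compared with −0.76, −0.47, −0.43 and −0.37. Without control replicate 1 that of H2ac11 was −0.24. H1f2 stood at 2377, 1808 and 1188 CPM in control replicates 1, 2 and 3 and at 970.3 to 1116 CPM in Setdb1-sgRNA cells. The control libraries differed among themselves more than the Setdb1-sgRNA libraries did, with a median SD per gene of 0.154 against 0.0678 on the log2 scale. Rpph1, the RNA of RNase P, took 1.83% and 1.81% of reads in control replicates 1 and 2, 0.673% in control replicate 3 and 0.507% to 0.632% in Setdb1-sgRNA cells. Histone genes took 2.11 ± 0.27% of reads in control and 1.75 ± 0.128% in Setdb1-sgRNA cells (exact two-sided permutation p = 0.2), ribosomal protein genes 1.98 ± 0.204% and 1.69 ± 0.0458% (p = 0.1 in the exact test), and the 10 most abundant genes 6.07 ± 0.548% and 4.76 ± 0.102% (p = 0.1 in the exact test), where 0.1 is the smallest p that 3 against 3 allows. Without control replicate 1 the difference between the groups was −0.227% of reads for histone genes and −0.179% for ribosomal protein genes, against −0.366% and −0.288% with all libraries.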

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

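The filter at 0.5 CPM set aside 3035 genes with at least 10 reads, and a look at their reads with edgeR, chosen after the data were seen, called 12 of them higher and 1 lower in Setdb1-sgRNA cells. These genes entered no comparison above. Of the 12, 5 had no read in any control library: Tex19.1, a germline gene silenced in most somatic tissues, with 35, 31 and 35 reads in the Setdb1-sgRNA libraries, Sycn with 33, 28 and 24, Cd209f with 21, 23 and 19, D730045A05Rik with 34, 34 and 51, and Gm8016 with 21, 17 and 15. Epcam had 1 read over the control libraries and 63 over the Setdb1-sgRNA libraries. The gene that was lower was Gja4, with 105 reads in control and 16 in Setdb1-sgRNA cells.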

How the results depend on the processing

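Keeping only control replicate 3, removing the length and GC trend, and leaving Rpph1 out of the totals were added after the data were seen; the other settings were planned. Setdb1 stayed lower in all settings run, with log2 fold changes from −0.70 (control replicate 3 alone) to −0.53 (without control replicate 3). The count of higher genes ranged from 548 to 2983 and that of lower genes from 229 to 1839 when 1 library was left out, and with a log2 fold change of at least 1 they were 176 and 37 by construction. Lower genes numbered 440 with no filter, where 18459 genes were tested, and 1621 with DESeq2 on the recovered reads; the cause of the latter was not tested. Against control replicate 3 alone the median log2 fold change over the tested genes was 0.008, compared with 0.0448 with all libraries. That fit holds no spread between controls, so its numbers of called genes are not compared here. With the replicate number as a block, 1999 were higher and 1352 lower, and camera called the mast cell, basophil and eosinophil list as lower (adjusted p = 0.0307). Same-numbered libraries had deviation correlations of 0.165, −0.151 and 0.181, and not every library correlated best with its own number. These few values neither show nor exclude that the numbers pair the samples. Of 7 gene lists called by camera, 0 were called with an estimated correlation, where the NK ligand list had an adjusted p of 0.265. The estimate was 0.0033 for the ribosome biogenesis list, below the preset 0.01, and between 0.0343 and 0.214 for the other called lists. Losing the call in this setting is therefore not by itself a sign of correlated members. Fry, which does not compare a list with other genes, called 10. Among these were lists that camera had not called, all as higher. They were the p53 target (fry adjusted p = 0.00482), H3K9 methylation and HUSH (0.00559), interferon and receptor (0.00659), dendritic cell (0.022) and monocyte and macrophage lists (0.031). With fry and in the other settings the NK ligand list stayed between 0.000266 and 0.00743, and the type I interferon list, never called, between 0.478 and 0.994. Over 96 named genes other than Setdb1, 1852 of 1994 values kept direction and side of the threshold, 139 lost the call (83 of them with 1 library left out), 3 gained it and 0 called values changed sign. Depth limits low genes: 1 read is worth 0.0232 to 0.0249 CPM.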

Other observations

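The tests on neighbouring genes, on granule genes, on transcript length and on Rpph1, and the genes named in this part, were chosen after the values were seen; the GC test and the splits of the libraries were not. Several strongly expressed genes outside the naming rule rose in all Setdb1-sgRNA libraries. Gsto1, a glutathione transferase gene, rose 8.53-fold from 108.4 ± 4.88 to 924.5 ± 26.4 CPM, and Adam8, a membrane protease gene, 9.92-fold from 67.0 ± 8.69 to 664.6 ± 20.4 CPM. The ubiquitin ligase gene Itch rose 5.55-fold and the SLAM family receptor gene Cd84 8.91-fold (mean ± SD, n = 3; limma adjusted p between 2.45e-09 and 8.27e-08 for these 4 genes).

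Raised genes often lay side by side. On chromosome 16, between 36156811 and 36455392, 7 stefin and cystatin genes in a row rose, with Csta2 37.1-fold (114-fold without control replicate 1) and Stfa1 15.3-fold higher. On chromosome 11, between 114889152 and 114989886, the receptor genes Cd300a, Cd300lb, Cd300c and Cd300ld rose, with Cd300c 14.3-fold and Cd300ld 5.38-fold higher. The 176 genes raised at least 2-fold formed 30 adjacent pairs, where permuted positions gave 2.58 on average and 10 at most in 10000 draws (permutation p = 0.0001, the smallest they can give), which argues against placement by chance. All 1432 placed raised genes formed 301 pairs against 173 on average (permutation p = 0.0001), and the 37 genes lowered at least 2-fold formed 2 pairs against 0.106 (permutation p = 0.0053), so adjacency was not limited to rises. Overlap of RefSeq spans does not account for it, since 28 pairs had separate spans there. The annotation used for counting is not known, so reads counted for both of a pair under other gene models were not excluded. Reads shared within families do not account for 6 pairs of different families, such as Adam8 with Spef1l and Itch with Ahcy (1.67 on average and 7 at most by chance, permutation p = 0.0057), but for the other 24 pairs, of one family or with an uncharacterised or zinc finger gene, shared reads cannot be told apart from separate rises because gene totals hide which copy a read came from. A candidate explanation for the 6 pairs is loss of silencing over stretches of chromatin, an untested hypothesis that would not cover the lowered pairs.

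The azurophil granule genes Mpo, Elane, Prtn3 and Ctsg all fell, Prtn3 from 1348 ± 74.6 to 627.4 ± 31.9 CPM and Ctsg from 905.5 ± 11.6 to 607.3 ± 8.83 CPM, with a median log2 change of −1.44, while the other 16 granulocyte markers had a median of 0.37, with 8 higher and 2 lower, Gfi1 and the less firm Fcnb (adjusted p of 0.0995 without control replicate 2, of 0.104, 0.119 and 0.144 without Setdb1-sgRNA replicates 1, 2 and 3, of 0.0748 with the length and GC trend removed and of 0.0937 against control replicate 3 alone). These 16 include genes for receptors and transcription factors, so the comparison does not separate granule types. Dilution by other cells would lower the genes of the diluted cells alike. The 27 stem cell, progenitor and leukaemia genes had a median of −0.10 with an SD of 0.523. Of these, 5 rose and 6 fell, with Cebpa, Kit and Prom1 at −1.29, −0.95 and −0.93. Which of the 27 genes other cells would also express was not measured, so this median cannot decide on dilution. The gap of 1.81 stayed at 1.71 with the length and GC trend removed and at 1.65 against control replicate 3 alone, which argues against both as its whole cause. A change in maturation stage of the cells may underlie it, a hypothesis that was not tested.

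The control libraries lay apart from each other, at −29.8, −21.9 and −10.3 for replicates 1, 2 and 3 on the first principal component (69.5% of the variance, Setdb1-sgRNA libraries at 19.5 to 21.9) and at 16.2, −8.42 and −14.95 on the second (14.8%), which set control replicate 1 apart. Across 11680 genes, which are not independent replicates, the mean of control replicates 1 and 2 minus control replicate 3 followed transcript length (Spearman rho = −0.241, with −0.242 for control replicate 1 and −0.188 for control replicate 2 alone) more than GC content (rho = 0.0859). That value argues against a steady rise or fall with GC content as the cause. A rho does not show a curved dependence, so GC content is not excluded. Genes under 1000 nt exceeded genes over 3000 nt by 0.247 on the log2 scale, far more than the loss of −0.0168 that the extra Rpph1 reads imply, which argues against Rpph1 as the cause. The change between the groups followed length too (rho = 0.222, and 0.101 against control replicate 3 alone), in part by construction because these differences share control libraries. A length-dependent difference in library preparation may contribute, and no biological explanation was tested. Separately, Rn45s, a ribosomal precursor, stood at 0.196% of reads in Setdb1-sgRNA replicate 1 and at 0.00622% to 0.0201% in the other libraries.

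The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1439 higher genes, 826 lower genes and 7 called lists, and the highest of the other splits gave 0 genes in one direction and 6 lists. Each other split mixes libraries of both groups, so the difference between the groups enters its spread. Its lack of called genes is therefore no measure of what chance would give.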
